A study of Mus musculus with 8 samples.

How the data were processed

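The data are gene counts from 8 RNA sequencing libraries of the mouse cell lines EHE6 (n = 3), EHE17 (n = 3) and EHE26 (n = 2). Per the labels, RNA was extracted with the RNeasy Mini kit and libraries were made after polyA selection with the NEBNext Ultra II kit. The authors aligned reads with HISAT2 to mm10 and give no version. The counting tool, the annotation and the strand setting are not stated. The deposited values are raw counts per Ensembl gene for 55401 gene identifiers, and the file of each sample holds the same values as its column in the series table (8 of 8). Of the identifiers, 55141 are in GENCODE release M21 (GRCm38), which gave symbols and positions, and the others held at most 0.0181% of the counts of a library. Total counts were 44620965 to 96237665 per library. Binomial intervals (95%, Wilson) and the floor of 3 counts, taken over the libraries of a line for a gene with no read, cover counting error only.

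Counts were normalised with TMM factors and filtered with filterByExpr by line, which left 18882 genes, 22 of them without a place in the annotation. The model was the quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 on all 8 libraries with the line as the only term. P-values were adjusted over all tested genes with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Principal components used log2 CPM with a prior count of 2. The common biological coefficient of variation was 0.600, and 0.427 with the set of libraries as a term.

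The comparisons, tests, thresholds, gene lists and the rule for named genes were chosen before the data were examined. Named genes are, for each comparison, up to 8 higher and 8 lower genes with the largest absolute log2 fold change among called genes whose libraries do not overlap and whose mean in the higher line is at least 10 CPM, leaving out predicted genes, Xist and Y-linked genes. Added to these are up to 5 genes per direction that set a line apart from both others, up to 4 called members of each gene list described, any members that a count of 5 or fewer needs, and a fixed group of genes named whatever their values. Single genes of the region around Cdkn2b, interferon ligand genes and genes read in the first set alone were chosen after their values were seen.

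Of 31 gene lists, 27 were tested in the 3 comparisons, 81 tests in all, with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, and a Benjamini-Hochberg adjustment over all 81. The lists were: endothelial (pan), lymphatic, arterial and venous endothelial, fibroblast and mesenchymal, smooth muscle and pericyte, macrophage and leukocyte, epithelial keratin and junction, YAP/TAZ-TEAD targets, Hippo pathway core, MAPK output, proliferation, p53 targets, INK4 locus and cell-cycle inhibitors, interferon response, MHC class I presentation, hypoxia and glycolysis, cholesterol synthesis, TGF-beta response and matrix, cytokines and NF-kB targets, ER stress and ATF4 targets, Notch pathway, WNT targets, immediate early, mitochondrially encoded, Hox and imprinted growth. Lists of mesothelial, hepatocyte and lung epithelial genes had fewer than 5 tested members and were not tested, and the sex chromosome genes served for values only. With an estimated correlation 5 of the 29 list calls held: the interferon response in both comparisons with EHE26, MHC class I presentation and Hox in EHE26 against EHE6, and Hox in EHE17 against EHE6. Of these, 4 held with the set as a term as well, and Hox in EHE26 against EHE6 did not. With fry, which asks whether the genes of a list move one way without comparing them with other genes, 11 of the 29 held.

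The pipeline was tested on simulated data of the same depth and spread, with 50 genes changed at each of 4 sizes. For EHE17 against EHE6 it recovered 0% of changes of log2 1, 36% of log2 2, 88% of log2 4 and 82% of log2 6. For EHE26 against EHE6 it recovered 0%, 10%, 86% and 84%, and for EHE26 against EHE17 0%, 12%, 78% and 88%. False calls were 2 of 105, 9 of 99 and 5 of 94. A list of 20 raised genes had a camera p-value of 2.65e-15 for EHE17 against EHE6, 1.01e-17 for EHE26 against EHE6 and 6.08e-13 for EHE26 against EHE17. Of 20 unchanged lists, 1, 0 and 1 fell under 0.05. Genes were drawn independently of each other and the lists at random, so this check says nothing about lists whose genes move together.

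Replicate numbers were checked as a possible pairing from how each library departs from the mean of its line. Across genes, which are not independent replicates, the departures of libraries with the same number in EHE6 and EHE17 correlated at 0.13, 0.18 and 0.57, so the replicate block was read beside that comparison. Replicate 1 of EHE6 correlated more with replicate 2 of EHE17 (0.54), and replicate 2 of EHE6 with replicate 1 of EHE17 (0.62). The EHE26 numbers correlated at 0.18 and -0.10 with EHE6 and at -0.06 and -0.11 with EHE17, so they were not taken as pairs. No 2 libraries were copies of each other. Alternatives were RLE factors, library totals alone, no low-count filter, replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, fitting only the lines compared, other fold thresholds, an estimated correlation and fry. Chosen after seeing the data were the set of libraries as a term, each set alone, the block with only EHE6 and EHE17 libraries, leaving out chromosomes 4, 10 and 16, and the simulation in which the sets differ. No library was left out of the main results.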

Results

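RNA was sequenced from 3 mouse cell lines of epithelioid hemangioendothelioma (EHE), a tumour of vascular endothelium that in patients often carries a fusion of WWTR1 with CAMTA1. Polyadenylated RNA was read from 3 libraries of EHE6, 3 of EHE17 and 2 of EHE26, named here by line and replicate number. The total count was 77491090, 69366708 and 44620965 for EHE6 replicates 1, 2 and 3. It was 75967830, 96237665 and 48521022 for EHE17 replicates 1, 2 and 3, and 55802651 and 47469274 for EHE26 replicates 1 and 2. The labels name the lines and state no further question, so each line was compared with each of the others. Levels are CPM, read counts scaled to the library size after TMM correction, given as the mean ± SD over the libraries of a line, with n = 3 for EHE6, n = 3 for EHE17 and n = 2 for EHE26. Changes are log2 fold changes ± standard error (SE) with the adjusted p from edgeR, and a gene is called where that p is under 0.05 and the absolute log2 fold change is at least 1. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these libraries. Positions are gene spans on the mouse genome build GRCm38 (mm10), counted from 1.

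All 3 lines had transcripts of the endothelial genes Pecam1, Cdh5 and Erg. Pecam1, an adhesion molecule of endothelial junctions, was at 1444 ± 244 CPM in EHE6, 1570 ± 163 in EHE17 and 1348 ± 74.7 in EHE26. Cdh5, which encodes VE-cadherin, was at 3275 ± 1987, 2884 ± 800 and 1996 ± 52.0 CPM in the same order, and the transcription factor Erg at 257 ± 190, 244 ± 14.5 and 177 ± 78.6 CPM. Kdr and Vwf, also endothelial, had lower means in EHE26 and were not called: Kdr was at 631 ± 538, 494 ± 223 and 73.9 ± 39.2 CPM, and Vwf at 13.3 ± 8.78, 3.36 ± 2.58 and 0.631 ± 0.148 CPM. EHE26 lies wholly in the second set of libraries described below. In that set the pan-endothelial list was also lower within EHE6 (median log2 difference -2.33) and EHE17 (-0.74). Kdr there was 3.45 log2 units higher in EHE17 than in EHE6. These means therefore do not tell the line from the set. The genes at the ends of the human fusion did not pass the test in any comparison: Wwtr1 was at 79.5 ± 9.24, 92.6 ± 21.4 and 96.0 ± 15.8 CPM, and Camta1 at 341 ± 68.0, 457 ± 121 and 355 ± 25.9 CPM. Gene counts such as these do not separate a fusion transcript from the unfused genes. The related coactivator Yap1 was at 147 ± 28.3, 195 ± 13.9 and 206 ± 4.06 CPM, and Tead1 at 180 ± 41.4, 184 ± 49.6 and 204 ± 10.3 CPM. Tead2 was at 82.5 ± 35.3, 111 ± 29.6 and 78.7 ± 27.6 CPM, Tead3 at 6.70 ± 10.3, 1.88 ± 0.464 and 11.2 ± 1.44 CPM, and Tead4 at 32.6 ± 10.5, 27.5 ± 2.49 and 35.6 ± 8.94 CPM. None of Yap1, Tead1, Tead2, Tead3, Tead4, Trp53, Kdr, Vwf, Prox1, Ccn1, Ccn2, Cdkn2a, Cdkn2b, Col1a1, Ptprc and Epcam was called in any of the 3 comparisons. The leukocyte gene Ptprc was at 0.869 ± 0.541 CPM in EHE6, 0.523 ± 0.201 in EHE17 and 0.643 ± 0.207 in EHE26. The Y-linked gene Ddx3y was at 69.8 ± 29.0 CPM in EHE6, 0.649 ± 0.602 in EHE17 and 0.0899 ± 0.00301 in EHE26, while Xist was at 12.2 ± 7.44, 458 ± 370 and 314 ± 27.3 CPM.

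The libraries fell into 2 sets that crossed the lines. Principal component 1 held 56.2% of the variance of log2 CPM, and the sets are the libraries with negative and with positive scores on it. The set explained 93.4% of that component and the line 48.4%. As the set was cut from that component, these shares do not weigh one against the other. The first set was EHE6 replicates 1 and 2 with EHE17 replicates 1 and 2, and the second set was EHE6 replicate 3, EHE17 replicate 3 and both EHE26 libraries. EHE17 replicate 3 lay in between, at 41.7 on component 1 against 128 for EHE6 replicate 3 and 126 and 148 for EHE26. Over the tested genes its closest library by Spearman correlation was EHE17 replicate 1 of the first set (0.938), ahead of EHE26 replicate 1 (0.935). EHE6 replicate 3 was less close to EHE6 replicates 1 and 2 (0.894 and 0.888) than to EHE26 replicates 1 and 2 (0.938 and 0.945). Its correlation with EHE17 replicate 3 was 0.921. The second set held fewer genes with a read, 20066 in EHE6 replicate 3 and 20682 in EHE17 replicate 3, against 24462 and 24698 in EHE6 replicates 1 and 2 and 25177 and 24641 in EHE17 replicates 1 and 2. The proliferation list was 1.78 log2 units higher at the median in EHE6 replicate 3 than in EHE6 replicates 1 and 2, and 1.70 higher in EHE17 replicate 3 than in its own replicates 1 and 2. The pan-endothelial list moved by -2.33 and -0.74 in the same libraries. Ccn2, a target of YAP and TAZ, was at 52.7, 87.7, 62.0 and 49.7 CPM in the first set and at 1.18, 1.85, 2.45 and 0.943 CPM in the second set, while the list of YAP/TAZ-TEAD targets as a whole moved by -0.02 in EHE6 and -0.29 in EHE17. Because EHE26 lies wholly in the second set, each comparison is also given with the set as a term beside the line, an alternative chosen after seeing the data.

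**Figure D1:**
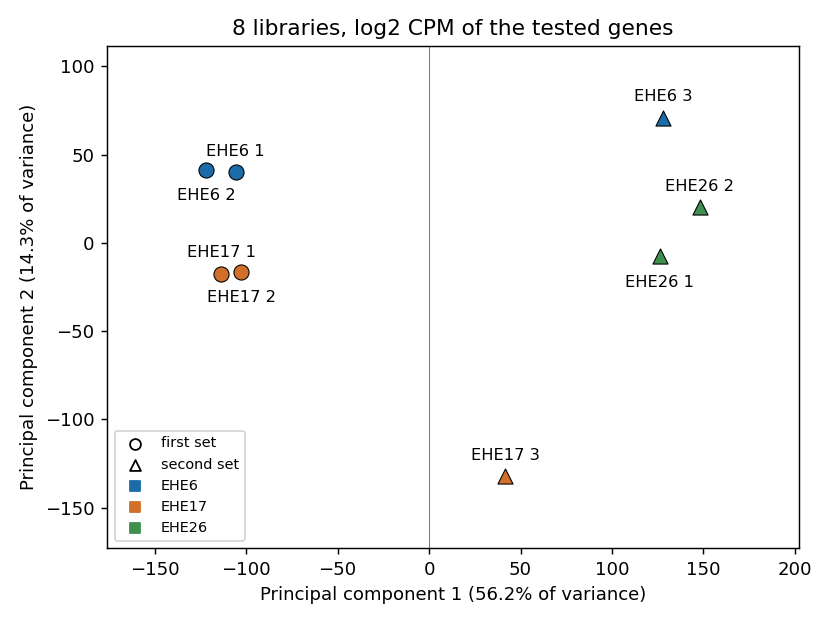
Principal components 1 and 2 of log2 CPM (arbitrary units) of the 18882 tested genes, 1 point per library, coloured by line, with circles for the first set and triangles for the second set. The first set lies left of 0 on component 1 (56.2% of the variance) and the second set right of it.

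EHE17 against EHE6. A lymphatic vessel gene, Hox genes of the B cluster and some interferon-inducible genes were higher in EHE17. Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), a hyaluronan receptor of lymphatic endothelium, was at 1057 ± 1123 CPM in EHE17 and 5.02 ± 1.22 in EHE6, a log2 fold change of 7.72 ± 0.95 (adjusted p = 0.0367). Its level differed within EHE17, at 476 and 342 CPM in replicates 1 and 2 and 2352 CPM in replicate 3. Hoxb7 (ENSMUSG00000038721, chromosome 11, 96286623 to 96290162), a homeobox gene of axial identity, was at 34.7 ± 6.88 CPM against 0.524 ± 0.132, a change of 6.04 ± 0.34 (adjusted p = 0.00191). The sodium channel gene Scn3a (ENSMUSG00000057182, chromosome 2, 65457118 to 65567627) was at 76.1 ± 28.2 CPM against 0.296 ± 0.170, a change of 7.97 ± 0.75 (adjusted p = 0.0158). Also higher were Npy (6.43 ± 0.73), Hoxb6 (5.08 ± 0.56), Clec4d (4.52 ± 0.56), Slc45a3 (4.43 ± 0.45), Nlrc5 (4.07 ± 0.50), Ifi44 (3.96 ± 0.51), Gdpd3 (3.91 ± 0.48), Ripk3 (3.84 ± 0.35) and Gbp3 (2.45 ± 0.27). Gbp3 has close relatives in the genome, so the split of its reads between copies is uncertain. Lower in EHE17 were Ltbp1, which binds latent TGF-beta (6.89 ± 2.18 CPM against 145 ± 33.5, -4.39 ± 0.39), and the stromal surface protein Cd248 (-3.91 ± 0.47). AI506816 (-4.13 ± 0.43), B3gnt3 (-3.44 ± 0.33), Adamts12 (-2.30 ± 0.28), Dpysl3 (-1.56 ± 0.21) and the Y-linked Ddx3y (-6.72 ± 0.88) were lower as well. Each of these genes was separated in all 3 libraries of each line, and among all tested genes such separation occurred in 12.2%, where chance gives 10%. Separation was part of the naming rule for the top genes, and all 27 called genes had it, so it gives no further support.

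In all, 27 genes were called between EHE17 and EHE6, 15 higher and 12 lower, and 1302 had an unadjusted p under 0.05. After adding the set as a term 102 genes were called, 61 higher and 41 lower, and these held all 27. Within the first set alone 102 genes were called, with 25 of the 27 among them, and within the second set alone 787, with 23 of the 27, where the spread comes from the EHE26 pair. The count was 5, 4 and 53 without EHE6 replicate 1, 2 and 3, 1 and 4 without EHE17 replicate 1 and 2, and 8 and 8 without EHE26 replicate 1 and 2. Of the 19 named genes, only Hoxb7 was called in each of the 8 fits that left out 1 library, and the sign was kept for all 19 in those fits. Without EHE6 replicates 1, 2 and 3 in turn, 3, 2 and 17 of the 19 were called, without EHE17 replicates 1, 2 and 3, 1, 2 and 12, and without EHE26 replicates 1 and 2, 4 and 4. The correlations given above argue against the numbers as pairs for replicates 1 and 2 of these lines. With replicate number as a block, the adjusted p was 0.05003 for Clec4d, Adamts12 and Gdpd3, just above the threshold, and 0.0819 for Dpysl3. That block with only the EHE6 and EHE17 libraries in the fit, chosen after seeing the data, called 23 genes, 16 of the 27 among them. It kept 13 of the 19 named genes, and the adjusted p was 0.0558 for Clec4d, 0.0937 for Gdpd3, 0.0988 for Adamts12, 0.115 for Nlrc5 and 0.210 for both Dpysl3 and Gbp3.

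Among the gene lists, the interferon response list was higher in EHE17 than in EHE6: 2 of its 24 members were called (Ifi44 and Gbp3), 16 when adjusted over the list alone, and the median change was 1.48. The adjusted p of the list was 4.93e-30, and adjusted p = 0.0570 with an estimated correlation. The MHC class I presentation list, the machinery that shows peptides to T cells, was higher with 1 of 12 members called (Nlrc5), 9 adjusted over the list alone, and a median of 1.51. The test of the list gave an adjusted p of 5.21e-21, and adjusted p = 0.0910 with an estimated correlation. The Hox list was higher with 2 of 23 tested members called (Hoxb6 and Hoxb7), 6 adjusted over the list alone, and a median of 1.54. Camera gave an adjusted p of 4.93e-23, and adjusted p = 0.0279 with an estimated correlation, and within the second set alone the adjusted p was 0.194. The lymphatic endothelial list was higher with 1 of 11 tested members called (Lyve1), 2 adjusted over the list alone, and a median of 2.58. Its adjusted p was 2.96e-08, and adjusted p = 0.0907 with an estimated correlation. Prox1, a transcription factor of lymphatic identity in that list, was at 200 ± 80.4 CPM in EHE17 and 29.4 ± 24.2 in EHE6 and was not called (2.77 ± 1.22, adjusted p = 0.729).

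Lists with smaller shifts also passed between EHE17 and EHE6, with no member called in any of them. The fibroblast and mesenchymal list was lower in EHE17 (median -1.04, adjusted p = 0.0398), with 1 member higher and none lower adjusted over the list alone, and adjusted p = 0.821 with an estimated correlation. The smooth muscle and pericyte list was lower (median -1.03, adjusted p = 0.00217, 0 adjusted over the list alone), with adjusted p = 0.531 with an estimated correlation. The cholesterol synthesis list was lower (median -0.47, adjusted p = 0.00586, 1 adjusted over the list alone), with adjusted p = 0.852 with an estimated correlation. The list of WNT targets was lower (median -0.87, adjusted p = 0.0362, 0 adjusted over the list alone), with adjusted p = 0.299 with an estimated correlation. The list of cytokines and NF-kB targets was higher (median 0.60, adjusted p = 0.00953, 1 adjusted over the list alone), with adjusted p = 0.295 with an estimated correlation. The proliferation list was lower (median -0.51, adjusted p = 0.0324, 0 adjusted over the list alone), with adjusted p = 0.897 with an estimated correlation. Each of these 6 calls was lost in at least 1 fit that left out a library. Without EHE6 replicate 3 the adjusted p was 0.165 for the fibroblast list, 0.160 for cholesterol synthesis and 0.160 for WNT targets, and for proliferation the median was 0.37 and the adjusted p 0.231. Without EHE17 replicate 1 it was 0.386 for cholesterol synthesis, 0.0516 for WNT targets and 0.960 for proliferation, and without EHE17 replicate 2 0.0575 for WNT targets and 0.248 for proliferation. Without EHE17 replicate 3 it was 0.970 for the fibroblast list, 0.310 for smooth muscle and 0.140 for WNT targets. Without EHE26 replicate 1 it was 0.0510 for the fibroblast list, and for cytokines it was 0.133 and 0.0900 without EHE6 replicates 1 and 2. Some of these calls ended with a median no smaller than with all libraries: 0.78 and 0.75 for cytokines, -0.95 and -1.33 for WNT targets without EHE17 replicates 1 and 2, and -1.04 for the fibroblast list without EHE26 replicate 1. In the second set alone the adjusted p was 0.374 for cholesterol synthesis, 0.145 for WNT targets and 0.653 for cytokines, whose median there was -0.14. Without chromosomes 4, 10 and 16, a choice made after seeing the data, it was 0.0863 for the fibroblast list and 0.0785 for proliferation, and without the low-count filter it was 0.0524 for cytokines.

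EHE26 against EHE6. Interferon-inducible genes and MHC class I genes were higher in EHE26. Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960), an interferon-inducible gene, was at 466 ± 103 CPM in EHE26 and 1.48 ± 0.871 in EHE6, a log2 fold change of 8.31 ± 0.63 (adjusted p = 0.00159). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), a transcription factor of the interferon response, was at 687 ± 171 CPM against 2.99 ± 3.63, a change of 7.86 ± 1.14 (adjusted p = 0.0202). The antiviral genes Oas3 (8.15 ± 0.92), Mx1 (7.83 ± 0.88), Usp18 (7.77 ± 0.87), Oas2 (7.72 ± 0.92) and Zbp1 (7.86 ± 1.22) were also higher, as was the chemokine gene Cxcl10 (5.91 ± 0.98). H2-Q7 was at 301 ± 35.5 CPM against 0.691 ± 0.309 (8.77 ± 1.11, adjusted p = 0.0106). H2-Q6 (8.76 ± 0.82), H2-Q7 and Oas1g (8.31 ± 1.31) have near-identical neighbours in their families, so the share of their reads that belongs to each copy is uncertain.

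Other genes set EHE26 and EHE6 apart. Ptges, which makes prostaglandin E2, was at 194 ± 142 CPM in EHE26 and 0.920 ± 0.200 in EHE6 (7.72 ± 0.72, adjusted p = 0.00296). Also higher were Ackr4 (8.25 ± 1.24), Hoxb7 (6.51 ± 0.36), Hoxb6 (5.83 ± 0.60), Nlrc5 (6.53 ± 0.58), Ripk3 (4.70 ± 0.38), Ccdc80 (4.96 ± 0.68), the arterial gene Bmx (3.61 ± 0.62), the endothelial and progenitor antigen Cd34 (2.65 ± 0.36) and Spry4 (2.27 ± 0.25), an inhibitor induced by MAPK signalling. Ackr4 was at 54.3 ± 69.1 CPM in EHE26, so its level differed widely between the libraries of that line. Lower in EHE26 were Fez1 (1.29 ± 0.548 CPM against 48.1 ± 4.69, -5.22 ± 0.40, adjusted p = 0.00159), Eps8l1 (-4.75 ± 0.39), AI506816 (-4.86 ± 0.54) and Kctd12b (-4.88 ± 0.61). Ebf1 (-7.87 ± 1.34), Kbtbd11 (-7.72 ± 0.93), Nox4 (-7.37 ± 1.15), Sox13 (-6.23 ± 1.09) and the tight junction gene Ocln (-4.17 ± 0.69) were lower too. Xist (4.69 ± 0.81) was higher in EHE26, and the Y-linked genes Ddx3y (-9.57 ± 1.24) and Kdm5d (-8.31 ± 1.44) were lower.

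In all, 237 genes were called between EHE26 and EHE6, 207 higher and 30 lower, and 3000 had an unadjusted p under 0.05. This balance was not kept by DESeq2 (653 higher and 944 lower) or with the replicate block (674 and 785). The block set EHE26 against the level of EHE6 replicates 1 and 2, of the first set. The fit without EHE6 replicate 3, given below, left EHE6 with those libraries alone. Calls of the block and of that fit therefore do not tell the line from the set. When the set was a term 356 genes were called, 296 higher and 60 lower, with 195 of the 237 among them. Within the second set alone, where EHE6 has 1 library, 601 were called, with 188 of the 237. With the set as a term 39 of the 41 named calls held, and the adjusted p was 0.0975 for Bmx and 0.0696 for Hsd17b7. The count was 65, 85 and 1625 (829 higher and 796 lower) without EHE6 replicate 1, 2 and 3, 151 and 145 without EHE17 replicate 1 and 2, and 77 and 88 without EHE26 replicate 1 and 2. Called in each of the 8 fits that left out 1 library were H2-Q6, Ifi44, Fez1, Eps8l1, Hoxb7, Hoxb6, Nlrc5, Ripk3, Ptges, H2-T23 and Psmb9, 11 of the 41. Without EHE6 replicates 1, 2 and 3 in turn, 14, 23 and 41 of the 41 were called, without EHE17 replicates 1, 2 and 3, 31, 30 and 39, and without EHE26 replicates 1 and 2, 16 and 21. Libraries of the pair of lines did not overlap for 31.3% of tested genes. Chance gives 20% where libraries are exchangeable, which they are not here, since EHE26 lies wholly in the second set.

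The interferon response list was higher in EHE26 than in EHE6, with 20 of 24 members called, 22 adjusted over the list alone and 21 with the set as a term, and a median change of 6.04. The adjusted p of the list was 7.1e-105, and adjusted p = 0.0123 with an estimated correlation. The MHC class I presentation list was higher with 11 of 12 members called, 12 adjusted over the list alone, and a median of 4.30. The test of the list gave an adjusted p of 3.05e-52, and adjusted p = 0.0292 with an estimated correlation. Among its members H2-T23 was at 423 ± 7.47 CPM in EHE26 and 8.99 ± 0.300 in EHE6, the immunoproteasome gene Psmb9 at 47.3 ± 15.9 against 1.26 ± 0.314, and H2-Q4 at 354 ± 52.0 against 12.5 ± 10.6. H2-Q4 belongs to the family of H2-Q6 and H2-Q7, so the share of its reads that is its own is uncertain too. The Hox list was higher with 5 of 23 tested members called (Hoxb3, Hoxb4, Hoxb6, Hoxb7 and Hoxb8), 6 adjusted over the list alone, and a median of 1.32. Camera gave an adjusted p of 2.97e-14, and adjusted p = 0.0313 with an estimated correlation, but 0.136 with that correlation and the set as a term, and within the second set alone it was 0.0782. The cholesterol synthesis list was higher with 2 of 20 members called (Lss, 2.59 ± 0.34, and Hsd17b7, 2.19 ± 0.35), 13 adjusted over the list alone, and a median of 1.64. Its adjusted p was 1.6e-14, and adjusted p = 0.295 with an estimated correlation. The mitochondrially encoded genes were lower with 1 of 13 called (mt-Nd2, 149 ± 24.9 CPM against 709 ± 136, -2.25 ± 0.34), 9 adjusted over the list alone, and a median of -2.25. Their adjusted p was 2.22e-10, and adjusted p = 0.295 with an estimated correlation. The set as a term moved their median to -1.30 (camera adjusted p = 7.34e-09, and 0.0640 with an estimated correlation). Between the sets they were also lower within lines, by -1.28 in EHE6 replicate 3 and -0.79 in EHE17 replicate 3.

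The pan-endothelial list was lower in EHE26 than in EHE6 at a median of -1.42 (adjusted p = 0.00179), and adjusted p = 0.852 with an estimated correlation. Its 1 called member, Cd34, was higher, and adjusted over the list alone 1 was higher and 4 lower. After adding the set as a term the median of this list was -0.18 and its adjusted p 0.747, in the second set alone 0.65 and 0.342, and without EHE26 replicate 2 the adjusted p was 0.0724. The list of epithelial keratin and junction genes was lower, with 0 of 11 members called, 0 adjusted over the list alone, and adjusted p = 0.00403. Its median was -6.16, or -3.93 with members that had no read set to their bound of 3 counts over the line. It had adjusted p = 0.682 with an estimated correlation, 0.227 with the set as a term and 0.188 in the second set alone. Between the sets this list was also lower within lines, by -1.25 in EHE6 replicate 3 and -1.66 in EHE17 replicate 3. The first set also held reads of genes such as the kidney gene Kap, at 27.6 and 115 CPM in EHE6 replicates 1 and 2, with no read in the second set. The source of those reads stays open. The fibroblast and mesenchymal list was higher (median 0.66, adjusted p = 0.00185) with 0 of 18 called, 1 adjusted over the list alone, and adjusted p = 0.531 with an estimated correlation. The set as a term raised the median of this list to 2.03 (camera adjusted p = 2.2e-07, and 0.364 with an estimated correlation). The list of cytokines and NF-kB targets was higher (median 0.54, adjusted p = 0.00179) with 1 of 15 called (Cxcl10), 6 adjusted over the list alone, and adjusted p = 0.149 with an estimated correlation and 0.0815 in the second set alone. Without EHE26 replicate 1 the median of this list was -0.21, while the test stayed higher (adjusted p = 0.00622). The list of MAPK output genes was higher (median 0.34, adjusted p = 0.0114) with 1 of 13 called (Spry4), 1 adjusted over the list alone, and adjusted p = 0.412 with an estimated correlation. It had an adjusted p of 0.104 with the set as a term, 0.727 in the second set alone and 0.0534 without EHE6 replicate 1.

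**Figure D2:**
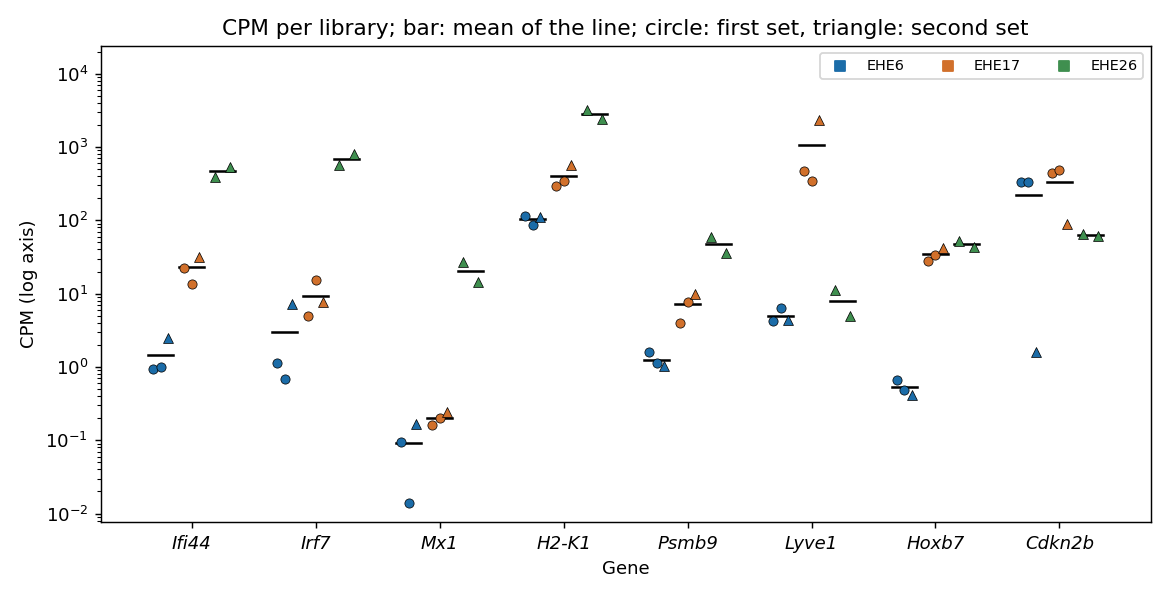
CPM (log axis) of 8 genes in each library, with circles for the first set, triangles for the second set and a bar at the mean of each line. Ifi44 is at 393 and 539 CPM in EHE26 and at most 32.0 CPM in the other libraries, and Cdkn2b is at 1.58 CPM in EHE6 replicate 3.

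EHE26 against EHE17. Interferon-inducible genes such as Oas2 and the MHC class I gene H2-K1 were higher in EHE26, and the lymphatic genes Lyve1 and Mmrn1 were lower. Oas2 was at 36.8 ± 27.1 CPM in EHE26 and 0.0848 ± 0.0131 in EHE17 (8.72 ± 0.96, adjusted p = 0.0104). H2-K1, a classical MHC class I heavy chain gene, was at 2813 ± 583 CPM against 400 ± 142 (2.81 ± 0.35, adjusted p = 0.0130). B3gnt3 (ENSMUSG00000031803, chromosome 8, 71690756 to 71701789), a glycosyltransferase gene, was at 293 ± 10.6 CPM against 4.31 ± 1.74 (6.09 ± 0.38, adjusted p = 0.00460). Lyve1 was at 8.04 ± 4.30 CPM against 1057 ± 1123 (-7.04 ± 1.11, adjusted p = 0.0331), and Plvap, which forms the diaphragms of endothelial fenestrae, at 490 ± 67.9 against 4467 ± 1296 (-3.19 ± 0.38, adjusted p = 0.0121).

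Further genes higher in EHE26 than in EHE17 were Ptges (8.04 ± 0.73), Col14a1 (7.89 ± 0.96), Pdzrn3 (7.58 ± 1.17), Ackr4 (7.40 ± 1.18), the pericyte proteoglycan gene Cspg4 (6.08 ± 0.95), Ccdc80 (5.82 ± 0.71), Cd34 (4.53 ± 0.39), Cd248 (3.91 ± 0.49), Ltbp1 (3.42 ± 0.39), Adamts12 (2.53 ± 0.30), Spry4 (2.21 ± 0.25) and Dpysl3 (1.68 ± 0.22). Within EHE26 the libraries differed widely for Col14a1 (236 ± 274 CPM) and Ackr4 (54.3 ± 69.1 CPM). Of interferon-inducible genes, Oas3 (8.29 ± 0.93), Mx1 (6.68 ± 0.83), Ifit3 (6.37 ± 0.65), Irf7 (6.19 ± 1.06) and Iigp1 (5.29 ± 0.49) were higher. Ifi205 (8.42 ± 0.96), Gbp2b (7.95 ± 1.23), Phf11b (7.69 ± 1.12) and Oas1g (7.46 ± 1.24) were higher as well and have close relatives in the genome, so the split of their reads between copies is uncertain. Lower in EHE26 were the lymphatic gene Mmrn1 (0.344 ± 0.269 CPM against 93.9 ± 43.6, -8.07 ± 1.34), Susd4 (-10.18 ± 1.78), Pir (-7.62 ± 1.01), Scn3a (-7.11 ± 0.86), Nox4 (-6.81 ± 1.12), Npy (-6.06 ± 0.87), Sox13 (-6.03 ± 1.08), Eps8l1 (-5.78 ± 0.41), Kctd12b (-5.31 ± 0.63), Gdpd3 (-4.36 ± 0.58) and Ocln (-4.31 ± 0.70).

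In all, 203 genes were called between EHE26 and EHE17, 168 higher and 35 lower, and 3132 had an unadjusted p under 0.05. Here too DESeq2 (669 higher and 1030 lower) and the replicate block (918 and 942) did not keep the balance. The block set EHE26 against the level of EHE17 replicates 1 and 2, of the first set, as did the fit without EHE17 replicate 3. When the set was a term 319 genes were called, 243 higher and 76 lower, with 159 of the 203 among them, and within the second set alone 828, with 166 of the 203. With the set as a term 41 of the 45 named calls held, and the adjusted p was 0.0633 for Oas1g, 0.0726 for Ackr4, 0.0742 for Cspg4 and 0.0939 for Irf7. The count was 113, 120 and 1411 (755 higher and 656 lower) without EHE6 replicate 1, 2 and 3, 7 and 2 without EHE17 replicate 1 and 2, and 43 and 21 without EHE26 replicate 1 and 2. B3gnt3 and Eps8l1 were called in each of the 8 fits that left out 1 library. Without EHE6 replicates 1, 2 and 3 in turn, 31, 31 and 45 of the 45 were called, without EHE17 replicates 1, 2 and 3, 3, 2 and 33, and without EHE26 replicates 1 and 2, 12 and 8. Libraries of the pair of lines did not overlap for 39.0% of tested genes, against 20% by chance for exchangeable libraries, which the sets rule out here too.

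The interferon response list was higher in EHE26 than in EHE17, with 17 of 24 members called, 22 adjusted over the list alone and 14 with the set as a term, and a median change of 4.35. The adjusted p of the list was 7.36e-60, and adjusted p = 0.0279 with an estimated correlation. The MHC class I presentation list was higher with 5 of 12 members called, 12 adjusted over the list alone, and a median of 2.64; H2-T23 (2.97 ± 0.47), Tap1 (2.93 ± 0.30), H2-D1 (2.84 ± 0.50) and H2-K1 were among them. The test of the list gave an adjusted p of 1.51e-23, and adjusted p = 0.0570 with an estimated correlation. The cholesterol synthesis list was higher with 4 of 20 members called, among them Cyp51 (2.89 ± 0.45), Lss (2.48 ± 0.34) and Sqle (2.30 ± 0.29), 17 adjusted over the list alone, and a median of 1.74. Camera gave an adjusted p of 1.01e-20, and adjusted p = 0.198 with an estimated correlation. The lymphatic endothelial list was lower with 2 of 11 tested members called (Lyve1 and Mmrn1), while adjusted over the list alone 5 were lower and 2 higher, and its median was -3.88. Its adjusted p was 0.00991, and adjusted p = 0.531 with an estimated correlation, and with the set as a term the median was -0.89 with an adjusted p of 0.0355. In the second set alone its median was -1.80 with an adjusted p of 0.128. The mitochondrially encoded genes were lower with 1 of 13 called (mt-Nd2, -2.11 ± 0.34), 10 adjusted over the list alone, and a median of -1.90. Their adjusted p was 1.99e-08, and adjusted p = 0.348 with an estimated correlation. The set as a term moved their median to -1.10 (camera adjusted p = 1.71e-07, and 0.0753 with an estimated correlation).

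The fibroblast and mesenchymal list was higher in EHE26 than in EHE17 at a median of 1.83 (adjusted p = 9.47e-06), with 0 of 18 members called and adjusted p = 0.295 with an estimated correlation. Adjusted over the list alone 8 of its members were higher and 1 lower. The list of MAPK output genes was higher at a median of 0.45 (adjusted p = 0.00142), with 1 of 13 called (Spry4), 3 adjusted over the list alone, and adjusted p = 0.295 with an estimated correlation. The pan-endothelial list was lower at a median of -1.22 (adjusted p = 0.00310), with Cd34 higher and Plvap lower among 29 members, the same numbers adjusted over the list alone, and adjusted p = 0.852 with an estimated correlation. After adding the set as a term its adjusted p was 0.623, in the second set alone it was 0.109, and without EHE26 replicate 2 it was 0.0816. The proliferation list was higher at a median of 0.60 (adjusted p = 0.00996), with 0 of 24 called, 0 adjusted over the list alone, and adjusted p = 0.882 with an estimated correlation. When the set was a term its median was -0.28 with an adjusted p of 0.0545, in the second set alone -0.25 with 0.00733, and without EHE17 replicate 1 the adjusted p was 0.338. The share of counts from the mitochondrial genome was 0.294% (95% Wilson interval 0.293 to 0.296) and 0.271% (0.270 to 0.273) in EHE26 replicates 1 and 2, against 0.853% (0.850 to 0.855) in EHE6 replicate 3 and 0.723% (0.721 to 0.726) in EHE17 replicate 3. In the first set it was 1.44% and 1.75% in EHE6 replicates 1 and 2 and 1.52% and 1.39% in EHE17 replicates 1 and 2.

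Genes that set 1 line apart from both others were counted from the same comparisons. EHE26 had 113 genes higher than in both other lines, among them Oas3, Ptges, Oas2, Oas1g and Ackr4, and 14 lower, among them Nox4, Sox13, Kctd12b, Eps8l1 and Ocln. EHE17 had 6 genes higher, among them Scn3a, Lyve1, Npy and Gdpd3, and 6 lower, among them B3gnt3, Ltbp1, Cd248, Adamts12 and Dpysl3. EHE6 had 8 genes lower than in both other lines, among them Hoxb7, Hoxb6, Nlrc5, Ifi44 and Ripk3, and 6 higher, among them AI506816. With the set as a term the counts were 166 higher and 31 lower for EHE26, 11 and 16 for EHE17, and 9 and 35 for EHE6. Independent lists of these sizes would share 1.84 genes higher and 0.0556 lower for EHE26, 0.0278 and 0.107 for EHE17, and 0.0191 and 0.164 for EHE6. The pair of comparisons behind each count shares the libraries of that line, which adds to the overlap, and in 20 simulated data sets with no difference between lines or sets the mean count was 0 in each case except 0.05 for EHE6 lower. Single comparisons in those data sets called a mean of 0.05 (EHE17 against EHE6), 0.05 (EHE26 against EHE6) and 0.1 genes (EHE26 against EHE17). With so few calls they cannot measure how much the shared libraries add. In 20 others, chosen after seeing the data, the sets differed as they do in EHE6 and EHE17 and the lines did not. Each of the 6 counts by edgeR was then 0, and with the set as a term all were 0 except a mean of 0.1 for EHE26 higher. With the line as the only term no gene was called between any pair of lines there, so these runs cannot measure the overlap either. They also assume that EHE26 shares that difference between the sets. In the counts that follow, leaving out EHE6 replicate 3 left EHE6 with libraries of the first set alone. Its comparison with EHE26 was then also one between the sets. The count of 113 was 40, 53 and 535 without EHE6 replicate 1, 2 and 3, 5 and 1 without EHE17 replicate 1 and 2, and 27 and 15 without EHE26 replicate 1 and 2. The count of 14 was 3, 4 and 442, then 1 and 1, then 3 and 1, in the same order of libraries. For EHE17 the counts of 6 higher and 6 lower became 0 and 1 without EHE6 replicate 1, 0 and 0 without EHE6 replicate 2 and without EHE17 replicate 1, 0 and 1 without EHE17 replicate 2, 2 and 1 without EHE26 replicate 1, and 0 and 0 without EHE26 replicate 2. For EHE6 the counts of 8 lower and 6 higher became 2 and 2 without EHE6 replicate 1 and without EHE6 replicate 2, 26 and 10 without EHE6 replicate 3, 1 and 0 without EHE17 replicate 1, 1 and 2 without EHE17 replicate 2, 2 and 2 without EHE26 replicate 1, and 4 and 2 without EHE26 replicate 2.

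Of the 27 lists tested, 13 were called in no comparison. Their smallest adjusted p over the 3 comparisons was 0.0869 for the Notch pathway, 0.221 for hypoxia and glycolysis, 0.221 for imprinted growth genes, 0.248 for YAP/TAZ-TEAD targets, 0.261 for the Hippo pathway core, 0.290 for TGF-beta response and matrix and 0.321 each for venous endothelial genes, p53 targets and ER stress and ATF4 targets. It was 0.557 for macrophage and leukocyte genes, 0.578 for arterial endothelial genes, 0.785 for the INK4 locus and cell-cycle inhibitors and 0.832 for immediate early genes. In YAP/TAZ-TEAD targets 1 of 23 members, Ccdc80, was called in each comparison with EHE26. The median of a list and its test had opposite signs in 13 of the 81 tests and the mean and the test in 9, and 0 of these passed the threshold.

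Other settings called lists that were not called in that comparison with all libraries and the line as the only term, and for some lists in opposite directions. With the replicate block, planned although the EHE26 numbers do not pair, proliferation was higher in EHE26 than in EHE6 (median 0.98, adjusted p = 3.9e-06), and Notch (-1.29, 0.0284) and smooth muscle genes (-1.63, 0.0179) were lower. Its term for replicate 3 rests on EHE6 and EHE17 alone. EHE26 was thus set against the level of replicates 1 and 2, which are of the first set, and the difference between the sets stayed in these comparisons. The block also called epithelial keratin (-6.09, 7.95e-05), Notch (-1.34, 0.00390) and imprinted growth genes (-2.15, 0.0101) lower in EHE26 than in EHE17, and imprinted genes higher in EHE17 than in EHE6 (0.9998, 0.0361). The set as a term instead called proliferation lower in EHE26 than in EHE6 (-0.84, 1.51e-06) and imprinted genes higher in EHE26 than in EHE6 (2.01, 8.87e-07) and EHE17 (1.26, 0.000280), and in EHE17 than in EHE6 (1.20, 0.0479). It also called TGF-beta response and matrix higher in EHE26 than in EHE6 (0.69, 0.0205) and EHE17 (0.88, 0.00267), and smooth muscle higher in EHE26 than in EHE17 (2.50, 0.00616). None of these 7 calls with the set held with an estimated correlation: the adjusted p was 0.691 for proliferation, 0.0982, 0.2498 and 0.430 for imprinted genes, 0.235 and 0.143 for TGF-beta and 0.493 for smooth muscle, in the order above. In the second set alone proliferation was lower (-0.78, 7.5e-09), imprinted genes higher (3.07, 0.00921) and leukocyte genes lower (-0.79, 0.0156) in EHE26 than in EHE6. There smooth muscle (4.42, 0.0299) and TGF-beta (0.91, 0.0407) were higher in EHE26 than in EHE17, and hypoxia higher in EHE17 than in EHE6 (0.78, 0.0118). Without the low-count filter epithelial keratin (-4.90, 0.0260) and Notch (-1.18, 0.0449) were lower in EHE26 than in EHE17, as was Notch without chromosomes 4, 10 and 16 (-1.32, 0.0446).

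Leaving out single libraries gave further list calls. Without EHE6 replicate 3 the adjusted p was 0.000150 for pan-endothelial genes, 0.0224 for epithelial keratin genes and 0.0474 for mitochondrially encoded genes, all lower in EHE17 than in EHE6. In EHE26 against EHE6 proliferation was then higher (median 0.98, 0.00294), while hypoxia (0.0164) and Notch (0.0283) were lower. Proliferation had that direction with the block too, and the opposite one with the set as a term and in the second set alone. Both this fit and the block set EHE26 against EHE6 at the level of the first set. Within lines the proliferation list was higher in the second set, by 1.78 in EHE6 and 1.70 in EHE17. The higher proliferation therefore goes with the difference between the sets. Notch was also lower in EHE26 than in EHE17 (0.0464). For EHE17 against EHE6 epithelial keratin genes were lower without EHE17 replicate 2 (0.0260), and imprinted genes higher without EHE6 replicate 2 (0.0443) and EHE17 replicate 3 (0.00291). For EHE26 against EHE17 smooth muscle was higher without EHE17 replicate 2 (0.0268), and epithelial keratin genes (0.00125) and Notch (0.0408) lower without EHE17 replicate 3. That last fit left EHE17 with libraries of the first set alone. Without EHE26 replicate 2 epithelial keratin genes were lower (0.0326) and the test of YAP/TAZ-TEAD targets higher (0.0406), with a median of -0.08.

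EHE6 replicate 3 differed from EHE6 replicates 1 and 2 along whole chromosomes. On chromosome 4 the median log2 difference was -0.79 (95% interval of the median over genes -0.86 to -0.73), with 414 of 484 genes lower, and on chromosome 16 it was -0.78 (-0.88 to -0.63), with 204 of 245 genes lower. On chromosome 10 it was 0.35. On chromosome 15 it was -0.33, but EHE17 replicates 1, 2 and 3 (-0.55, -0.41 and -0.56) and EHE26 replicates 1 and 2 (-0.52 and -0.53) also lay below EHE6 replicates 1 and 2 there. EHE17 replicate 3 against its own replicates 1 and 2 gave -0.02 on chromosome 4 and 0.05 on chromosome 16. Cdkn2b (ENSMUSG00000073802, chromosome 4, 89306299 to 89311039), an inhibitor of cyclin-dependent kinases, was at 333, 335 and 1.58 CPM in EHE6 replicates 1, 2 and 3, at 444, 482 and 88.0 CPM in EHE17 replicates 1, 2 and 3, and at 64.7 and 61.3 CPM in EHE26. Its neighbour Cdkn2a was at 3.88, 4.56 and 0.0210 CPM in EHE6 replicates 1, 2 and 3, and neither gene was called in any comparison. Genes are not independent replicates, and this difference is that of a single library.

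**Figure D3:**
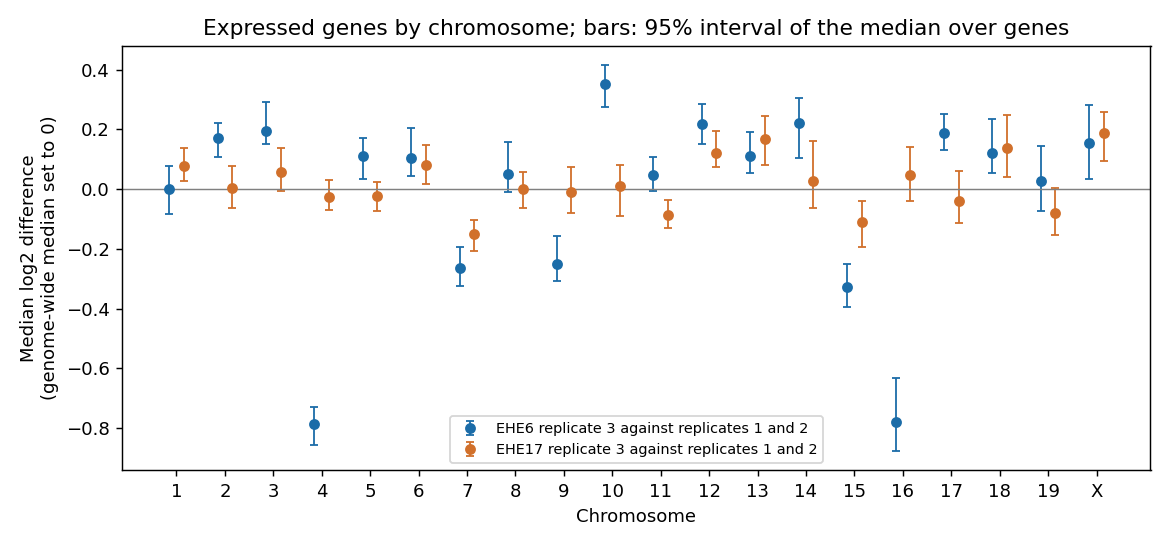
Median log2 difference of expressed genes on each chromosome between replicate 3 and the mean of replicates 1 and 2, for EHE6 (blue) and EHE17 (orange), with the genome-wide median set to 0 and bars for the 95% interval of the median. EHE6 is lowest on chromosomes 4 (-0.79) and 16 (-0.78), and EHE17 stays near 0 on both.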

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

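The settings with the set of libraries as a term, with 1 set alone, with the block on EHE6 and EHE17 only and without chromosomes 4, 10 and 16 were chosen only after the result was seen; the others were planned. Comparisons are given in the order EHE17 against EHE6, EHE26 against EHE6 and EHE26 against EHE17, and counts that set a line apart as higher and lower for EHE6, EHE17 and EHE26. RLE factors, library totals and both other fold thresholds left all of these counts within 1.5 times the reported ones. Without the low-count filter 142, 547 and 745 genes were called and the line counts were 12 and 45, 30 and 30, and 255 and 104, over 31318 genes. DESeq2 called 393, 1597 and 1699, with 45 and 96, 87 and 64, and 414 and 607, and 40.9% and 39.4% of its calls were higher in the comparisons with EHE26 against 87.3% and 82.8%. Fitting only the lines compared gave 7, 131 and 790, with 2 and 1 for EHE6, 1 and 1 for EHE17 and 4 lower for EHE26. The replicate block gave 1459 (674 higher) and 1860 (918 higher) for the EHE26 comparisons, 15 lower for EHE6 and 496 higher and 635 lower for EHE26. There EHE26 was set against the level of replicates 1 and 2, of the first set, so these counts hold the difference between the sets. The set term gave 102, 356 and 319, with 35 lower for EHE6, 11 and 16 for EHE17 and 31 lower for EHE26. The second set alone gave 787, 601 and 828, with 51 and 189, 156 and 217, and 202 and 32, and the first set alone gave 102. Of 29 list calls, 5 were made with an estimated correlation and 11 with fry.

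Leaving out each library in turn, the counts ranged from 1 to 53 (EHE6 replicate 3 left out) for EHE17 against EHE6, from 65 to 1625 for EHE26 against EHE6 and from 2 to 1411 for EHE26 against EHE17. The line counts ranged from 0 to 10 higher and 1 to 26 lower for EHE6, 0 to 9 higher and 0 to 7 lower for EHE17, and 1 to 535 higher and 1 to 442 lower for EHE26, and list calls from 25 to 32. The proliferation median of EHE17 against EHE6 ranged from -1.24 to 0.37. The 1625 calls of EHE26 against EHE6 came without EHE6 replicate 3, where that comparison was also one between the sets. A line left with 1 library is assumed to vary like the other lines.

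Directions reversed in 14 values. The proliferation median of EHE17 against EHE6 was 0.37 without EHE6 replicate 3, and without EHE17 replicate 1, where the test changed sign, it was -0.10. With the set term the proliferation median was -0.84 and -0.28 and the imprinted growth median 2.01 and 1.26 in the EHE26 comparisons with EHE6 and EHE17, all past the threshold except -0.28. In the second set alone Kdr was 3.45 higher in EHE17 than in EHE6, and Cdkn2a and Cdkn2b were 6.38 and 5.32 higher in EHE26 than in EHE6. EHE6 is there replicate 3 alone, with Cdkn2b at 1.58 CPM against 333 and 335 in EHE6 replicates 1 and 2. Cdkn2a was at 0.0210 CPM against 3.88 and 4.56, so both of these reversals follow from that library. In the second set the median was -0.14 for cytokines and NF-kB targets in EHE17 against EHE6. In EHE26 against EHE6 it was 0.65 for pan-endothelial genes, -0.78 for proliferation and 3.07 for imprinted growth, and in EHE26 against EHE17 it was -0.25 for proliferation, past the threshold for proliferation and imprinted growth. For the other shifts the cause was not tested. Of the other values for named genes, 2571 stayed on their side of the threshold, 95 of them with the other sign, 478 lost the call and 58 gained it. For lists 1258 medians stayed, 110 of them with the other sign, 75 lost the call and 33 gained it. Those with the other sign passed the threshold in neither setting, except the cytokine median of EHE26 against EHE6, -0.21 without EHE26 replicate 1, where the test stayed higher.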

Other observations

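The tests of other-tissue RNA in the first set, of the set of libraries for the chromosomes and for the interferon response, and of leukocyte RNA were chosen only after the result was seen; the other tests were chosen before their results.

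Genes of the interferon family itself had few reads. Ifnb1 had 8 and 26 reads in EHE26 replicates 1 and 2, 2 in EHE17 replicate 2 and 0 in the other libraries. Ifng, Ifne, Ifnk, Ifnl2, Ifnl3 and the Ifna genes examined had 0 reads in all 8 libraries, which allows up to 3 counts over a line. Ifnz had 3, 0 and 0 reads in EHE6 replicates 1, 2 and 3, 5, 15 and 3 in EHE17 replicates 1, 2 and 3, and 6 and 4 in EHE26 replicates 1 and 2. Around Cdkn2b on chromosome 4, the neighbour Gm12606 was, like Cdkn2a and Cdkn2b, lower in EHE6 replicate 3, at 27.7, 31.4 and 0.546 CPM in EHE6 replicates 1, 2 and 3. Beyond it Mtap was at 129, 101 and 437 CPM, Klhl9 at 25.4, 29.2 and 35.2 CPM, and Dmrta1 on the other side at 0.108, 0.0706 and 17.7 CPM. These genes were chosen after their values were seen.

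The split of the libraries into 2 sets was seen in both EHE6 and EHE17. Of 9565 genes with a mean of at least 10 CPM, 483 were lower and 370 higher in the first set by 2-fold or more in both lines, where independence would give 106 and 91.0. As the sets were cut from principal component 1 of these same libraries, agreement above independence is in part built in. Another 76 genes had at least 1 CPM in all 4 libraries of the first set and no read in the second, among them the kidney gene Kap (27.6, 115, 80.5 and 22.8 CPM in EHE6 replicates 1 and 2 and EHE17 replicates 1 and 2) and the retinal gene Rgr (17.8, 27.0, 19.9 and 17.5 CPM). They held 0.0297%, 0.0580%, 0.0463% and 0.0236% of the counts of those libraries.

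The tests argue against depth and a trend on GC content and transcript length as the whole of that split. For RNA of other tissues the test argues only against an even dilution of all genes. A batch that the labels do not name would be a technical source too and was not tested. With every library thinned to the smallest total, the set cut before thinning still explained 92.7% of principal component 1 (55.2% of the variance). This argues against depth. A smooth trend on GC content and transcript length, covering 99.9% of the genes, explained 2.65% of the variance of the difference between the sets. If RNA of other tissues diluted all genes of these cells alike, scaling would leave the proliferation list level between the sets. It was 1.79 higher in the second set in EHE6 (lower quartile 1.404) and 1.72 higher in EHE17 (lower quartile 1.53). These values use log2 CPM with a prior count of 2, and the 1.78 and 1.70 given earlier use log2 of CPM plus 0.5. RNA that lacked proliferation genes and shared others with these cells would lower the list in the first set too. The test therefore cannot decide on such RNA. The source of the 76 genes stays open, as does RNA of other tissues. Growth state and an unrecorded batch stay open too, since the labels name neither, and no biological explanation was tested.

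EHE6 replicate 3 was lower than its own line on chromosomes 4 and 16. EHE17 replicate 3 shifted by -0.025 and 0.047 there, which argues against the set of libraries, and removing a trend on GC content and transcript length left -0.75 and -0.77. RNA of another of the 3 lines would need a donor as low, and the lowest of the other second-set libraries on chromosome 4 was at -0.074. A hypothesis that may account for it is the loss of a copy of chromosome 4 in these cells: 22 of 24 windows of 20 genes (91.7%) lay below 0.5 times the chromosome's shift, as did 12 of 12 on chromosome 16 and 19 of 341 on other autosomes. It was formed and tested on the same RNA data, which hold no DNA measurement, so a swap with a line outside the study stays open.

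The interferon response in EHE26 could be read as a technical difference. For the genes of the list, the values argue against the set of libraries and against leukocyte RNA as its source. Within the second set alone the list kept a median of 5.51 against EHE6 (lower quartile 3.77) and 4.22 against EHE17 (lower quartile 2.94). Leukocyte genes, 6 of which EHE6 also has at 1 CPM or more, gained a median of -0.133 CPM in EHE26 against 118.5 CPM for the interferon list. All 20 called members (100%) lie outside chromosome 17, but 0 members of the list lie on it, so that share could not have come out otherwise. Strain variants that change only the reads of H2 region genes could not move this list whatever its values, so its shift is no test of them. They stay open for the MHC class I genes on chromosome 17. An effect of such variants on genes elsewhere was not tested. The difference between the lines stays open as an untested biological explanation, as does any difference in how the EHE26 cultures were kept.

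For EHE17 against EHE6, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, the only 1 with as many, called 27 genes, and the highest of the others called 0. Among splits that part 3 pairs of replicate numbers as the real one does, the others had 434, 1251 and 956 genes with an unadjusted p under 0.05 by edgeR, against 1302 for the real one; they mix the lines. All 9 other splits had 118 to 1966 such genes, and no other tool was run on them.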
